A study of Mus musculus with 6 samples.

How the data were processed

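Total RNA of 6 mouse samples was sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols: 3 samples of GABAergic interneurons infected with AAV-scramble and 3 with AAV-shbrpf1. The title of each sample gives its group and a replicate number from 1 to 3, and the columns of the deposited table were matched to the samples by group and number. The labels call the source of the cells neural progenitors in one field and GABAergic interneurons in the others.

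The authors deposited a single table of 55335 genes with a value per sample. The header names no unit. The deposited values are read here as FPKM, since they are not whole, do not sum to a fixed total and, multiplied by transcript length, fall on repeated steps at the low end in single-exon genes. FastQC, StringTie and DESeq2 are named without versions or roles in the submitters' processing notes; the aligner, the annotation, any filter and the use of strand are not given in the sources used here. The same notes name the genome build mm9. However, of 55154 gene identifiers found in GENCODE M21, which annotates GRCm38, 54899 have the same start and end in the table, so coordinates are given as those of GRCm38. For 3225 identifiers the table gives no symbol, and 26 symbols appear in the form of a date. A sum over transcripts, as FPKM of a gene is, moves with the transcripts chosen, and if strand was not used it mixes genes that overlap.

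Depth was estimated from 11673 genes with a single exon, a single transcript and over 400 nt, in which the most common product of FPKM and length in kilobases was taken as 1 fragment. This gave 13.1 to 21.1 M fragments per library. Between 40.1% and 44.0% of values up to 5 steps lay on whole steps (tolerance 0.03 of a step), so whole reads were not recovered and no test for counts was used. Fragments of Brpf1 were estimated at its longest transcript (4826 nt); intervals from such counts cover counting error only. The number of genes above 0 ran from 18780 in AAV-shbrpf1 library 2 to 26132 in AAV-shbrpf1 library 1. Features of ribosomal RNA loci (AY036118, CT010467.1, Gm23935, Gm24270 and Mir6236) took 1.5% to 8.33% of implied fragments, and mitochondrially encoded genes 1.34% to 6.09%. Some values of 0 may be failed estimates: 22 genes, 11 of them protein coding, were listed at 0 in at least 1 library and at 5 FPKM or more in another.

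The design written before the data were examined gave a count test for counts and a test on a log scale for FPKM, and the second was used. Genes with a mean of at least 1 FPKM in a group were kept (12792), and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (trend, two-sided) for AAV-shbrpf1 minus AAV-scramble without covariates. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Differences on this scale understate changes of low genes. No scaling was added to the deposited values. Libraries were compared by Pearson correlation, principal components and sums of squares, and differences between replicate numbers were tested with limma's F test.

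Whether the shared replicate numbers pair the samples was decided from the values before calls were compared. Deviations from the group means correlated between same-numbered libraries at 0.87, 0.83 and 0.57 for numbers 1, 2 and 3, and at most at 0 with other numbers, so the numbers pair the samples; the labels do not say what a number stands for. Results with the number as a block are given where they change a call or a count.

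Gene lists (35, with 809 entries, of which 3 were not found in the table) were fixed at the same time. They cover GABA and MGE biology, the Brpf1 complexes, neuronal function, other cell types, stress and virus responses, metabolism and RNA quality. The 28 lists with at least 5 measured members were tested with camera (preset correlation 0.01) and adjusted over lists. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were alternatives. With an estimated correlation each tested list had a camera adjusted p of 0.978, and of 0.992 under the block. This held for interneuron subtype markers too, whose estimated correlation under the block was 0 (camera adjusted p = 0.323 at the preset). A value shared by every list cannot tell lists apart, and that form was not run on simulated data. A list that does not pass it may therefore still differ, and no call is decided by it.

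The genes named follow a rule fixed beforehand. Brpf1 comes first. Up to 10 genes past the threshold in each direction, with groups that do not overlap, would follow, skipping predicted and unnamed genes among them. Since fewer than 20 passed, the 5 genes of smallest p in each direction are named as not past the threshold. In each list up to 2 members per direction past the threshold are named, and where there are none its 2 most abundant; some genes that the rule would name are not reported here. Other genes are said to have been chosen after their values were seen.

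The fits were tested on simulated data with the real means and replicate differences of 12792 genes in 20 simulations, with 200 genes changed 2-fold or 4-fold. The spread of each gene was drawn from limma's fitted prior, and genes varied independently of each other. Without the block 0% of either size was recovered. With the block 48% of 2-fold and 82.3% of 4-fold changes were recovered, with 6.8 unchanged genes called on average. A list of 30 genes shifted by 0.5 was called in 100% of simulations by both fits, at an unadjusted camera p under 0.05 with the preset correlation. The simulated genes were not correlated, while correlations estimated under the block ran from -0.25 (histone genes) to 0.79 (cytosolic ribosomal proteins). The 100% may therefore overstate how well correlated lists are detected.

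Alternatives were quantile normalization, median centring, no filter, a filter of 5 FPKM, a pseudocount of 0.1, a required fold change of 2, the block, each library or pair left out, and loess corrections (span 0.5) for transcript length and GC content, known for 99.9% of tested genes from the longest transcript in GENCODE M21. Without the block, a library left out leaves its replicate number in a single group, so such fits mix virus with number. The sequence of the hairpin is not given in the sources used here, so matches of the hairpin to other transcripts were not examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.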

Results

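RNA was sequenced from 6 samples of cultured mouse GABAergic interneurons, the inhibitory neurons that release GABA, taken from C57BL/6 embryos at embryonic day 14.5. All were infected for 12 hours with an adeno-associated virus (AAV). In 3 of them the virus carried a short hairpin against Brpf1 (AAV-shbrpf1) and in the other 3 a scrambled hairpin (AAV-scramble). Brpf1 is a scaffold subunit of the histone acetyltransferase complexes built on Kat6a and Kat6b. The study asks what Brpf1 does in interneurons that arise in the medial ganglionic eminence (MGE), the ventral forebrain zone that produces cells of the somatostatin and parvalbumin classes. The time from infection to RNA harvest is not given in the sources used here. The files hold gene expression in FPKM, which is fragments counted relative to transcript length and library depth. Steps between low values put the depth of the AAV-scramble libraries 1, 2 and 3 at 14.3, 21.1 and 20.8 M fragments, and that of the AAV-shbrpf1 libraries at 19.3, 13.1 and 16.6 M. Nothing in the labels says whether the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

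Brpf1, the gene targeted, was 16% lower in library 2, 21.8% lower in library 3 and 4.9% lower in library 1 with AAV-shbrpf1 than in the AAV-scramble library of the same number. Its level was 3.29, 5.45 and 4.84 FPKM in the AAV-scramble libraries and 3.13, 4.58 and 3.78 FPKM in the AAV-shbrpf1 libraries. The group means were 4.53 ± 1.11 and 3.83 ± 0.723 FPKM (SD, n = 3), a ratio of 0.85. This difference was smaller than the spread between replicates. On the log2(FPKM + 1) scale it was -0.18 ± 0.26 (SE) with a 95% interval of -0.79 to 0.42 and an adjusted p of 1 (limma). An exact two-sided permutation test of the group means gave p = 0.4, where the smallest p that 3 samples against 3 allow is 0.1. Brpf1 was lower in 3 of 3 pairs, for which an exact two-sided sign-flip test gave p = 0.25, the smallest that 3 pairs allow. With the replicate number as a block the interval was -0.44 to 0.07. A level of 50% of the AAV-scramble mean would be a difference of -0.76 on this scale, which lies inside the first interval and outside the second. The libraries held an estimated 226 to 555 Brpf1 fragments, so that counting error alone was 4.2% to 6.6% of each value. In pair 1 it was 6.6% of the AAV-scramble value and 5.9% of the AAV-shbrpf1 value, each larger than the 4.9% between them. A drop in that pair therefore cannot be told from counting error. Brpf1 (ENSMUSG00000001632) lies on chromosome 6 from 113307137 to 113324860 on the plus strand in GRCm38 coordinates, where Gm15492 overlaps it on the minus strand. As the use of strand is not given in the sources used here, reads of these genes may have been mixed. A gene-level value also counts all 10 annotated transcripts, whether or not the hairpin matches them.

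**Figure D1:**
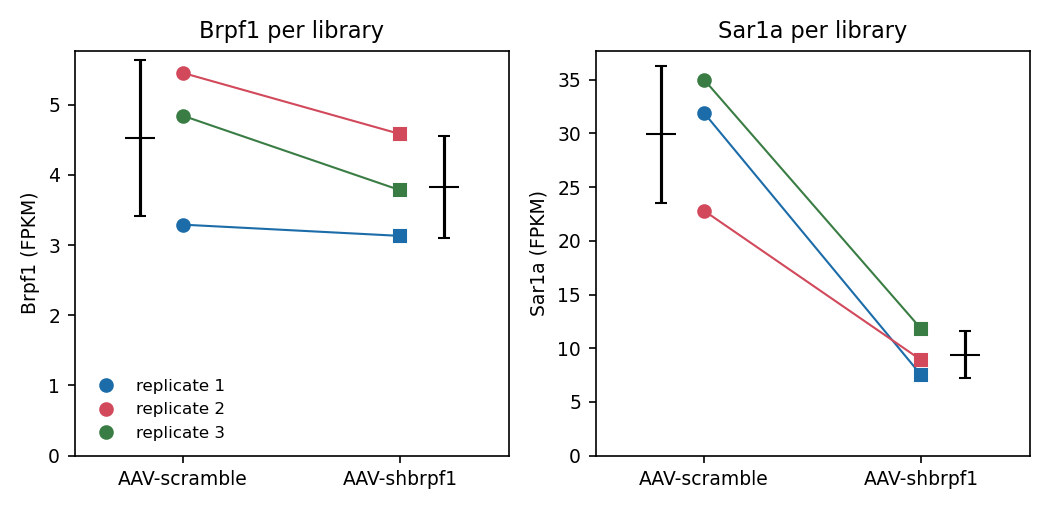
Expression of Brpf1 (left) and Sar1a (right) in FPKM in each library of the AAV-scramble (circles) and AAV-shbrpf1 (squares) groups, with lines joining libraries of the same replicate number and black marks for the group mean ± SD (n = 3). The Brpf1 values of the groups overlap (3.29 to 5.45 against 3.13 to 4.58 FPKM), while each Sar1a value with AAV-shbrpf1 (7.46 to 11.8 FPKM) lies below each value with AAV-scramble (22.8 to 35.0 FPKM).

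The libraries resembled each other by replicate number and not by virus. The replicate number held 86.9% of the sum of squares of log2(FPKM + 1), the group 3.6% and the remainder 9.5%, with 2, 1 and 2 degrees of freedom. Of the 12792 genes tested, 8876 (69.4%) differed between replicate numbers in limma's F test with the group in the model (adjusted p under 0.05). Pearson correlations across genes between libraries of the same number were 0.983, 0.978 and 0.984, against 0.872 to 0.947 between AAV-scramble libraries of different numbers. The somatostatin gene Sst, for example, stood at 178 and 232 FPKM in the libraries numbered 1 and at 394 to 564 FPKM in the others. Features of ribosomal RNA loci took 5.33% and 8.33% of the implied fragments in the libraries numbered 2 and 1.5% to 2.64% in the other 4. The differences between the viruses within a number did not follow one another across genes, with Pearson correlations of 0.02 between pairs 1 and 2, -0.09 between pairs 1 and 3 and -0.19 between pairs 2 and 3; genes are not independent replicates.

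**Figure D2:**
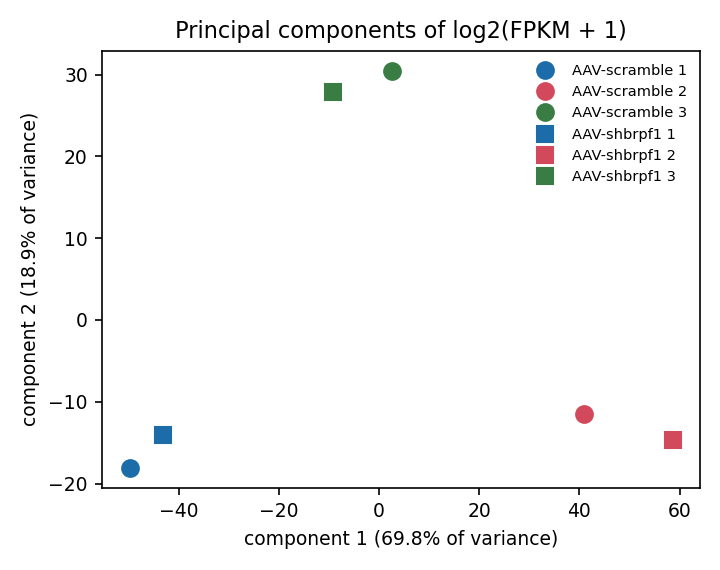
Principal components 1 and 2 of log2(FPKM + 1) over the 12792 genes tested, with 69.8% and 18.9% of the variance on the axes, color for the replicate number and shape for the virus. Libraries of the same number lie together, and neither axis separates AAV-scramble (circles) from AAV-shbrpf1 (squares).

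No gene passed the threshold between AAV-shbrpf1 and AAV-scramble. Sar1a, the small GTPase that starts COPII vesicle budding at the endoplasmic reticulum, had the smallest p among genes that were lower with AAV-shbrpf1. It measured 31.9, 22.8 and 35.0 FPKM with AAV-scramble and 7.46, 8.94 and 11.8 FPKM with AAV-shbrpf1, a log2 difference of -1.57 ± 0.27 (SE), lower in 3 of 3 pairs, with a limma adjusted p of 1. Among genes that were higher, Zdhhc24, of the DHHC palmitoyltransferase family, stood at 5.27 ± 1.00 against 1.98 ± 0.178 FPKM (SD, n = 3), and Brinp2, a neural protein of the BRINP family, at 12.1 ± 2.25 against 5.66 ± 1.52 FPKM. Kctd20, a BTB domain protein, measured 13.2, 15.6 and 15.2 FPKM against 9.86, 3.404 and 3.99 FPKM, and Tsku, which encodes the secreted leucine-rich protein tsukushi, 2.38 ± 0.723 against 0.563 ± 0.177 FPKM. None of these passed after Benjamini-Hochberg adjustment.

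The remaining genes that the rule named were low in both groups. AC124712.1 was listed at 0, 0 and 0.532 FPKM with AAV-scramble and at 4.83, 1.61 and 3.74 FPKM with AAV-shbrpf1. It lies on chromosome 12 from 73937653 to 73968375, is Gm49321 in GENCODE M21, and overlaps Hif1a and Snapc1 on the same strand, so its reads can be shared with theirs. Ak4, a mitochondrial adenylate kinase, stood at 2.88, 4.15 and 6.09 FPKM with AAV-scramble and at 0.457, 2.98 and 0.681 FPKM with AAV-shbrpf1, a log2 difference of -1.29 ± 0.43 (SE). Gm27027, which overlaps Alkbh3, was lower in the pairs numbered 1 and 2 only, at 3.19 and 6.42 against 0.126 and 0.117 FPKM. A transcript that the files list as Map2k7 under a second identifier (ENSMUSG00000109061, Gm49320 in GENCODE M21) overlaps the main Map2k7 gene and measured 1.81 ± 1.19 against 0.352 ± 0.349 FPKM (SD, n = 3). Gm22540, a small nuclear RNA gene of 117 nt, stood at 2.15 ± 1.08 against 0.905 ± 0.394 FPKM. For the 5 genes of smallest p in each direction, the log2 differences ranged from -1.57 to 1.85.

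**Figure D3:**
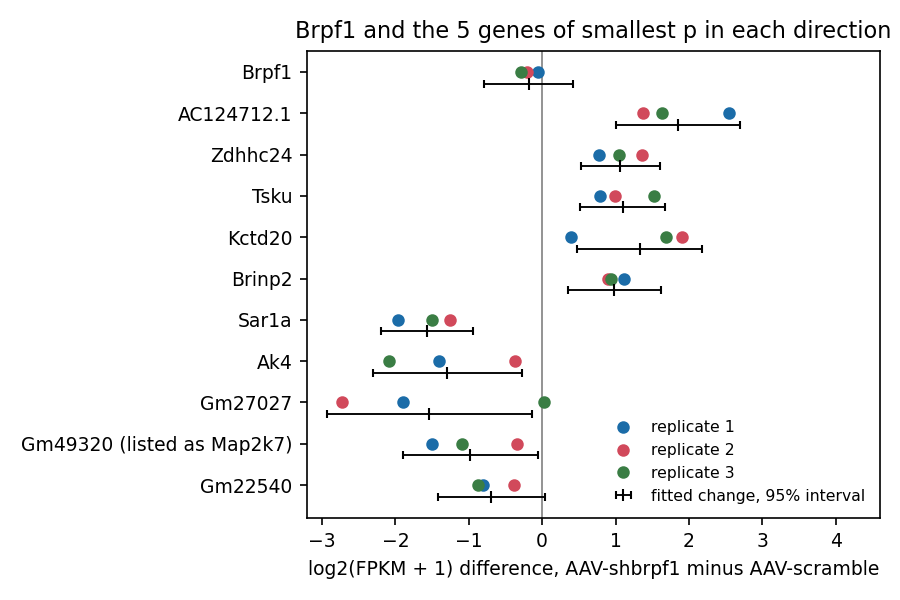
Difference in log2(FPKM + 1) between AAV-shbrpf1 and AAV-scramble for Brpf1 and the 5 genes of smallest p in each direction, with a colored point for each replicate number and a black bar for the fitted difference with its 95% interval (limma, not adjusted for the number of genes). Brpf1 has an interval from -0.79 to 0.42, and the points of Sar1a run from -1.96 to -1.26. The intervals are from the fit without the replicate number as a block.

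By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and 23 genes had an unadjusted p under 0.05 (19 higher, 4 lower), where chance would give about 640 of 12792 for libraries without pairs. The 3 other splits of the libraries that part all 3 pairs gave 23, 33 and 26 such genes. Groups that did not overlap were seen for 137 genes (1.07%, where chance gives 10% without pairs), 74 of them higher and 63 lower with AAV-shbrpf1, against 151, 164 and 151 genes in those splits. With the replicate number as a block, 0 genes passed as well, and the smallest limma adjusted p was 0.404, shared by Sar1a and Brinp2. Under the block 280 genes had an unadjusted p under 0.05 (145 higher, 135 lower). Swapping the labels within pairs gave 531, 1298 and 347 such genes, each more than the real arrangement. Leaving out the pair numbered 2 under the block gave 8 genes (5 higher, 3 lower), Sar1a among them at -1.73 (adjusted p = 0.01), and leaving out the pair numbered 3 gave 1, the chemokine gene Cx3cl1, looked up after its values were seen and lower with AAV-shbrpf1 in pair 3 (5.51 against 39.7 FPKM). In simulated data for this comparison the fit without the block recovered 0% of genes changed 4-fold and the fit with it 82.3%. The count of 0 from the first therefore says little. Simulated genes varied independently, so the 82.3% may not hold for these libraries.

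Other genes of small p under the block were looked up after their values were seen. Rsl24d1, which acts in assembly of the large ribosomal subunit, was higher in 3 of 3 pairs at 24.1 ± 3.30 against 14.2 ± 2.60 FPKM (SD, n = 3), and Ntmt1, a protein N-terminal methyltransferase, at 7.79 ± 1.84 against 3.99 ± 1.73 FPKM. The zinc finger gene Zfp579 stood at 5.14 ± 1.90 against 2.25 ± 0.621 FPKM, and Mapk1ip1 was lower in 3 of 3 pairs at 4.79 ± 3.02 against 8.32 ± 4.35 FPKM. With the block their limma adjusted p lay between 0.512 and 0.865. The short or low-level RNA genes Mir343, Gm22571 and Med9os followed at 0.512, 0.865 and 0.929.

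No gene that makes an interneuron inhibitory passed the threshold, with the block or without it. The fit without the block recovered 0% of simulated 4-fold changes. Its counts of 0, here and in the lists below, therefore say little. Of the 9 genes of GABA synthesis, release and uptake, 0 passed the threshold, and their median log2 difference was 0. The camera adjusted p of this list was 0.971, and 0.987 with the block. Gad1, a GABA-synthesizing decarboxylase, stood at 117 ± 34.3 FPKM with AAV-shbrpf1 and 126 ± 44.6 with AAV-scramble (SD, n = 3). Of the 19 GABA receptor and inhibitory postsynapse genes 0 passed, and the list did not (camera adjusted p = 0.96, and 0.578 with the block). Gabbr1 stood at 83.1 ± 25.5 and 80.3 ± 20.6 FPKM and Nlgn2 at 57.4 ± 20.7 and 56.5 ± 19.2. The median of that list was -0.26 in pair 2 and 0.15 in pair 3, where long-transcript and GC trends of the pairs also had opposite signs. It was called lower without AAV-scramble library 3 (camera adjusted p = 0.0419) and under the block without pair 3 (0.0101). With an estimated correlation these were adjusted p = 0.639 and 0.977. All lists called in the same fit shared that value, so here and below it decides no call.

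Among transcription factors of MGE interneurons, Lhx6 stood at 38.8 ± 10.5 FPKM with AAV-shbrpf1 and 41.0 ± 9.96 with AAV-scramble (SD, n = 3), and Dlx1 at 25.6 ± 9.25 and 27.95 ± 10.7. Of the 18 MGE factors, 11 genes of the caudal and lateral eminences and 13 interneuron subtype markers, 0 passed, and the camera adjusted p of the lists was 0.96, 0.96 and 0.53. The MGE list was called higher without AAV-scramble library 3 (adjusted p = 0.0146) and lower without AAV-shbrpf1 library 3 (0.0454). The caudal and lateral list was called lower without AAV-scramble library 1 (0.0288) or AAV-shbrpf1 library 3 (0.027), and the subtype list without AAV-scramble library 1 (0.0456). All of these had an adjusted p of 0.639 or larger with an estimated correlation. Ppp1r1b and Meis2, of the caudal and lateral list, measured 16.6 ± 16.2 and 10.975 ± 4.13 FPKM with AAV-shbrpf1 and 16.2 ± 14.2 and 11.4 ± 4.39 with AAV-scramble. Among subtype markers Sst stood at 349 ± 103 and 403 ± 201 FPKM and Npy, encoding neuropeptide Y, at 117 ± 64.5 and 149 ± 95.1. Parvalbumin (Pvalb), a late marker, was at or below 0.586 FPKM in each library. The 9 genes of the Brpf1 acetyltransferase complexes, Brpf1 included, had a camera adjusted p of 0.96, with Meaf6 at 22.1 ± 4.18 and 22.2 ± 5.18 FPKM and Kat6a at 16.7 ± 7.26 and 16.7 ± 5.36. None of the 39 Hox genes, at some of which these complexes act in other tissues, reached 1 FPKM on average, and the most abundant, Hoxa5 and Hoxa9, were at or below 0.0964 and 0.0226 FPKM in each library.

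Lists of neuronal function held no gene past the threshold either. The list of 28 presynaptic release genes had a camera adjusted p of 0.971, with the complexin gene Cplx1 at 381 ± 174 FPKM with AAV-shbrpf1 and 371 ± 198 with AAV-scramble and Vamp2 at 307 ± 197 and 314 ± 217 (SD, n = 3). For the 34 voltage-gated channels (adjusted p = 0.579), Hcn2 measured 40.8 ± 30.3 and 38.9 ± 27.3 FPKM. The 25 genes of glutamate receptors and the excitatory postsynapse (adjusted p = 0.96) included Gria1 at 138 ± 17.7 and 136 ± 10.4 FPKM and Camk2b at 37.8 ± 19.0 and 43.0 ± 18.3. For the 38 genes of migration and axon guidance (adjusted p = 0.96), Efnb3 stood at 90.9 ± 19.1 and 87.9 ± 24.9 FPKM and Cdk5r1 at 74.6 ± 14.7 and 72.7 ± 16.8. The presynaptic list was called higher without AAV-scramble library 2 (adjusted p = 0.0438), the migration list lower without AAV-shbrpf1 library 3 (0.0374) and the channel list higher under the block without pair 2 (0.00438), each at an adjusted p of 0.867 or larger with an estimated correlation.

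Markers of other cell types were measured as well. Progenitor and glial genes were abundant: Fabp7 stood at 499 ± 301 FPKM with AAV-shbrpf1 and 499 ± 280 with AAV-scramble and Slc1a3 at 68.5 ± 27.3 and 67.8 ± 25.4 (SD, n = 3). The astrocyte markers Sparcl1 and Aldoc measured 86.4 ± 46.8 and 79.2 ± 22.8 FPKM against 85.4 ± 46.6 and 88.8 ± 32.0, and the oligodendrocyte lineage genes Olig1 and Olig2 119 ± 46.3 and 47.3 ± 10.9 against 123 ± 60.6 and 46.3 ± 13.7. Cycling cells were represented by Pcna at 19.0 ± 8.10 and 21.05 ± 8.29 FPKM and Rrm2 at 14.3 ± 1.30 and 14.9 ± 2.82. None of the 16 progenitor, 28 cell cycle, 13 astrocyte and 15 oligodendrocyte lineage genes passed, and each of these lists had a camera adjusted p of 0.96. Without AAV-scramble library 3 the progenitor, astrocyte and oligodendrocyte lists were called higher (adjusted p = 0.0146, 0.0144 and 0.0178). The oligodendrocyte list was called lower without AAV-scramble library 1 (0.0148) or AAV-shbrpf1 library 3 (0.027), and the cell cycle list under the block without pair 1 (0.0136). All of these had an adjusted p of 0.639 or larger with an estimated correlation. The glutamatergic transporter genes Slc17a7 and Slc17a6 stayed at or below 0.0461 and 0.666 FPKM, and of the glutamatergic markers only Bcl11b (27.97 ± 12.8 and 28.2 ± 13.6 FPKM) and Emx2 (3.05 ± 1.49 and 3.05 ± 1.35), which ventral forebrain cells also express, were measured. Microglia and macrophage genes were nearly absent from the measured set, with 2 of 16 measured, among them Cd68 at 1.11 ± 0.208 and 1.45 ± 0.990 FPKM, and Cx3cr1 listed at 0 in each library. Tagln (4.62 ± 6.86 and 4.88 ± 7.46 FPKM) and Acta2 led the 4 measured endothelial and mural genes. Acta2 was listed at 11.6, 0 and 0.407 FPKM with AAV-shbrpf1 and at 11.5, 0.0216 and 0 with AAV-scramble. The erythroid gene Hbb-bs was at or below 0.936 FPKM in each library.

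Lists of virus and stress responses did not differ between the groups past the threshold; both groups carried virus, so a response to AAV itself was not measured. Of 31 interferon response genes 5 were measured and 0 passed (camera adjusted p = 0.579), with B2m at 21.7 ± 9.54 FPKM with AAV-shbrpf1 and 21.8 ± 10.8 with AAV-scramble and Stat2 at 2.84 ± 0.770 and 3.06 ± 0.422 (SD, n = 3). The inflammatory list had 2 measured members, Vcam1 at 4.73 ± 2.13 and 4.26 ± 1.85 FPKM and Nfkbia at 3.75 ± 1.02 and 3.82 ± 1.06. For 17 p53 targets (adjusted p = 0.96) Bax measured 24.7 ± 5.05 and 24.7 ± 3.07 FPKM and Plk2 22.5 ± 2.63 and 23.5 ± 4.17. The unfolded protein response list (21 genes, adjusted p = 0.971) had Atf4 at 54.5 ± 23.5 and 55.6 ± 24.3 FPKM and Hspa5 at 42.9 ± 16.2 and 46.4 ± 11.7, and the heat shock list (13 genes, adjusted p = 0.579) Hsp90ab1 at 670 ± 195 and 701 ± 184 and Hspa8 at 305 ± 37.1 and 284 ± 20.04. The unfolded protein response list was called higher without AAV-shbrpf1 library 3 (adjusted p = 0.0374, and adjusted p = 0.867 with an estimated correlation).

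Several housekeeping lists had median differences of opposite sign in different pairs. The 78 cytosolic ribosomal protein genes had a median difference of 0.29 in pair 2, -0.25 in pair 3 and -0.02 in pair 1 (camera adjusted p = 0.96 over all libraries), with Rplp1 at 542 ± 240 FPKM with AAV-shbrpf1 and 497 ± 202 with AAV-scramble and Rps15 at 509 ± 141 and 529 ± 200 (SD, n = 3). Under the block the ribosomal list was called lower without pair 2 (adjusted p = 1.61e-12) and higher without pair 3 (adjusted p = 8.11e-11). These became adjusted p = 0.96 and adjusted p = 0.977 with an estimated correlation. Without the block it was called lower without AAV-scramble library 1 (0.000155) or AAV-shbrpf1 library 2 (0.0151) and higher without AAV-scramble library 3 (2.91e-14) or AAV-shbrpf1 library 1 (3.45e-07). The 8 nuclear long noncoding RNAs had medians of 0.04, -0.47 and 0.67 in pairs 1, 2 and 3 (adjusted p = 0.96), with Meg3 at 123 ± 76.7 and 105 ± 59.5 FPKM and Malat1 at 98.0 ± 75.8 and 94.5 ± 74.1. The 15 mitochondrially encoded genes had medians of 0.08, -0.50 and -0.05 in pairs 1, 2 and 3 (adjusted p = 0.579). The list was called lower with quantile normalization without the block (adjusted p = 0.00202) and with it (0.000714), and under the block with length correction (0.0182) or without pair 1 (0.000244). Without the block it was also called lower without AAV-scramble library 2 (0.0438) or AAV-shbrpf1 library 1 (1.62e-05), and each of these calls had an adjusted p of 0.938 or larger with an estimated correlation. Among its members were mt-Co1 at 8228 ± 4740.3 and 8719 ± 4720.5 FPKM and mt-Cytb at 3289.5 ± 2966 and 3108 ± 2187. For 65 nuclear genes of oxidative phosphorylation (adjusted p = 0.413) Atp5b stood at 278 ± 65.8 and 285 ± 47.2 FPKM and Cox6a1 at 263 ± 78.7 and 266 ± 62.0. The cholesterol list (21 genes, adjusted p = 0.96) had Hmgcs1 at 122 ± 62.1 and 131 ± 71.4 FPKM and Srebf2 at 50.8 ± 26.0 and 51.1 ± 25.2, and the glycolysis list (21 genes, adjusted p = 0.96) Gapdh at 217 ± 62.7 and 218 ± 52.4 and Aldoa at 216 ± 93.2 and 214 ± 96.1. Of 27 replication-dependent histone genes, 5 were measured (adjusted p = 0.413), with Hist1h1c at 9.89 ± 1.23 and 10.9 ± 1.57 FPKM and Hist1h2bc at 9.11 ± 4.28 and 10.3 ± 3.23. The oxidative phosphorylation list was called lower without AAV-shbrpf1 library 2 (adjusted p = 0.0101) and higher without AAV-shbrpf1 library 3 (0.00126), and under the block lower without pair 2 (0.00515) and higher without pair 3 (2.83e-07). The cholesterol list was called lower without AAV-scramble library 3 (2.95e-05) and higher without AAV-shbrpf1 library 3 (0.0374). The noncoding RNA list was called higher without AAV-scramble library 1 (0.0386) or AAV-shbrpf1 library 2 (0.0429), and under the block without pair 2 (4.05e-05). All calls of lists with libraries or pairs left out had an adjusted p of 0.639 or larger with an estimated correlation. Xist and Eif2s3y, of 4 measured sex-linked genes, stood at 22.4 ± 13.3 and 3.32 ± 3.06 FPKM against 22.2 ± 12.5 and 3.63 ± 3.65.

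Immediate early genes, which neurons switch on with activity, and extracellular matrix genes were the lists that passed with the replicate number as a block. Both were called lower with AAV-shbrpf1 under the block (camera adjusted p = 0.028 each), and not without it (adjusted p = 0.413 each). Both had an adjusted p = 0.992 with an estimated correlation, as had every other list tested under the block, so this value does not decide the calls. Without pair 1, 2 or 3 the block gave 2, 7 or 6 lists, and neither of these was among them without pair 1. All of those calls had an adjusted p of 0.938 or larger with an estimated correlation. Without the block the immediate early list was called lower without AAV-scramble library 3 (1.04e-09) or AAV-shbrpf1 library 2 (1.92e-06), and the matrix list without AAV-scramble library 2 (0.0438) or 3 (0.00606) or AAV-shbrpf1 library 1 (0.0117), each at an adjusted p of 0.639 or larger with an estimated correlation. None of the 17 measured immediate early genes and 23 matrix genes passed alone, over all genes or adjusted over the list alone. The median immediate early difference was -0.41 in pair 1, -0.05 in pair 2 and 0.05 in pair 3, and the matrix median -0.17, -0.07 and 0.03. In pair 1 Npas4 measured 8.82 against 14.6 FPKM and Fos 8.48 against 14.7 FPKM, while in pair 3 they stood at 1.19 against 0.720 and 0.771 against 0.469. Jun, the most abundant member, was at 27.3 ± 5.82 and 26.6 ± 6.57 FPKM, Npas4 at 11.3 ± 11.5 and 13.4 ± 12.1, and the matrix genes Timp2 and Sparc at 129 ± 33.6 and 36.7 ± 11.7 against 129 ± 30.5 and 41.9 ± 13.2 (SD, n = 3). Fibroblast and meningeal markers, a cell type list of 7 measured genes, had a median of -0.98 in pair 1, -0.01 in pair 2 and 0.01 in pair 3 and did not pass (adjusted p = 0.53, and 0.124 with the block). It was called lower without AAV-scramble library 3 (adjusted p = 0.000144) and under the block without pair 2 (0.000571) or 3 (0.0363), each at an adjusted p of 0.639 or larger with an estimated correlation. Its most abundant genes were Fbln1 at 3.81 ± 1.23 and 4.26 ± 1.71 FPKM and the collagen gene Col1a1, which was at 7.02 against 15.0 FPKM in pair 1 and at or below 0.223 FPKM in the other 4 libraries.

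**Figure D4:**
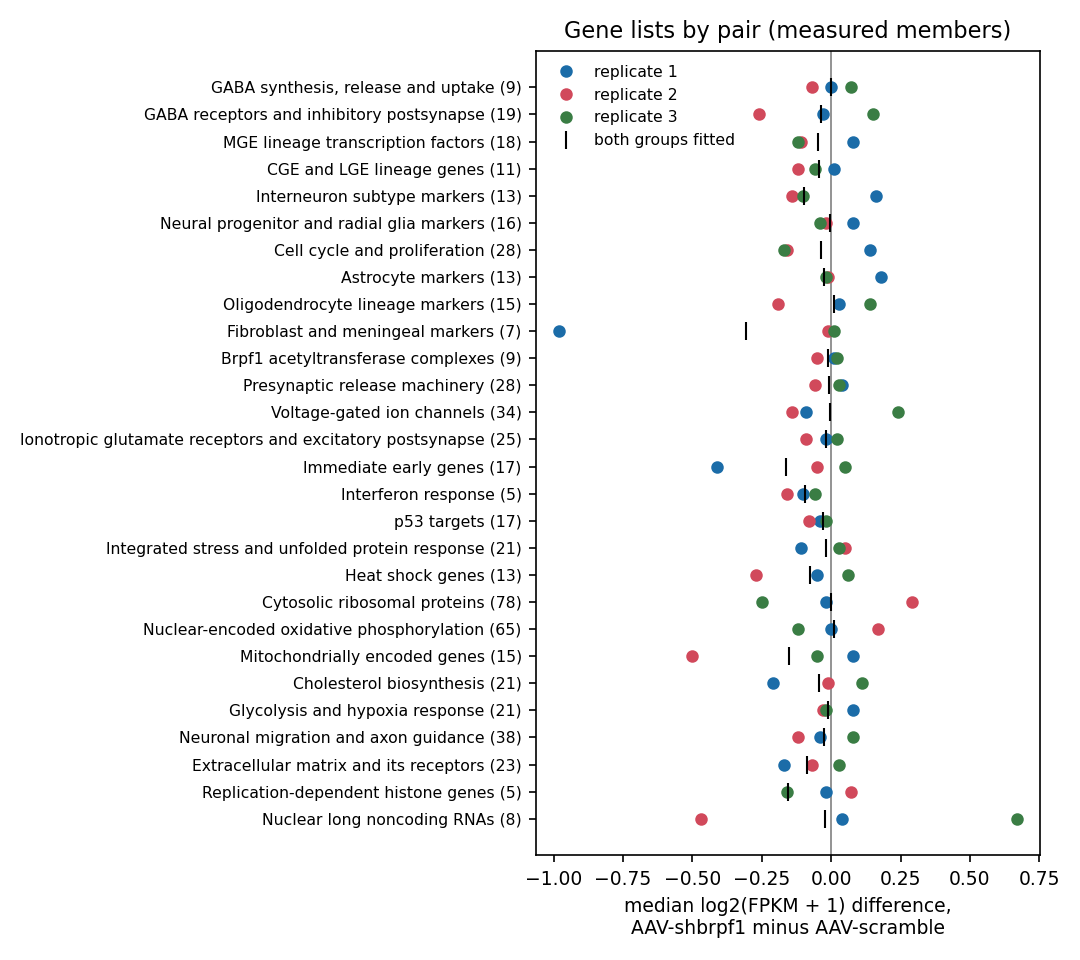
Median difference in log2(FPKM + 1), AAV-shbrpf1 minus AAV-scramble, for the 28 gene lists tested, with a colored point for each replicate number, a black tick for the median of the fitted differences over all libraries and the number of measured members in brackets. Points of the pairs lie on both sides of 0 in most lists, and the median farthest from 0 is that of fibroblast and meningeal markers in pair 1 (-0.98).

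In all, 0 of 28 lists passed in camera without the block, 0 with an estimated correlation and 0 in fry, where the block gave 2, 0 and 0, and 0 members passed in any of the 35 lists, over all genes or adjusted over the list alone. Camera's direction differed in sign from the median of its list for nuclear long noncoding RNAs, voltage-gated channels, progenitor, astrocyte, glycolysis and unfolded protein response genes, and the mean of oligodendrocyte lineage genes was below 0 with a median above it. Leaving out AAV-scramble library 1, 2 or 3 gave 5, 3 or 10 lists. Leaving out AAV-shbrpf1 library 1, 2 or 3 gave 3, 4 or 7, each at an adjusted p of 0.639 or larger with an estimated correlation. Each of these fits leaves a replicate number in a single group, so its calls mix virus with number. The calls took the direction that the list's median deviation in that number gives, as for MGE factors (0.39 in number 3). The exceptions were the subtype list without AAV-scramble library 1 and the ribosomal list without AAV-shbrpf1 library 2, with deviations of 0.01 and -0.02.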

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

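Corrections for GC content and length, median centring, every setting that combines the block with another choice, and leaving out both libraries numbered 2 were chosen after seeing the data. Genes past the threshold numbered 0 in 22 of 24 alternatives. In simulated data the fit without the block recovered 0% of changed genes, so the counts of 0 without it say little. A required fold change on top of a count of 0 can only give 0. With the replicate block and a pair left out the count ran from 0 to 8, with 0 to 5 genes higher and 0 to 3 lower: 0 without pair 1, 8 without pair 2 (among them Sar1a, Ak4, AC124712.1, Phf24, Ackr1, Dnal1 and March8) and 1 without pair 3 (Cx3cl1, higher); fewer libraries were fitted there, and the cause was not tested otherwise. Adjusted p over these alternatives was 0.00163 or larger. Genes at an unadjusted p under 0.05 numbered 9 to 229 without the block and 121 to 686 with it. Brpf1 was lower in 21 of 21 alternatives that kept it, by -0.36 to -0.06, with an adjusted p of 0.862 or larger; a filter of 5 FPKM removed it. Named genes kept their direction in 218 of 218 other values and their side of the threshold in 215. They were chosen for small p in these same libraries, which the alternatives refit whole or in part, so a kept direction is no independent support. Lists past the threshold numbered 1 with quantile normalization and 2 with the replicate block. With the block they numbered 2 with median centring, 3 with quantile normalization, 2 with GC correction and 3 with length correction. They numbered 4 without both libraries numbered 2, and 3 to 10 with a library left out. With the replicate block and without pair 1, 2 and 3 they numbered 2, 7 and 6. A library left out leaves its replicate number in a single group, so the counts of 3 to 10 mix virus with number. The cause of the other counts was not tested. With an estimated correlation, run for these after seeing the data, 0 of the 64 list calls passed (adjusted p of 0.639 or larger). This form was not run on simulated data, so these values do not decide the calls. The replicate block changed no other call. Count-based alternatives (DESeq2 and other size factors) were not run, because the values are FPKM. Depth limits Brpf1 to a counting error of 4.2% to 6.6% per library.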

Other observations

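The test without the replicate 1 pair, the test on Sar1b and the splits of all 6 libraries were chosen after the results they bear on were seen.

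Markers of other cells and immediate early genes differed between replicate numbers. Several fibroblast and matrix genes were higher in the libraries numbered 1: the osteopontin gene Spp1 measured 11.5 and 7.04 FPKM there and at most 0.145 FPKM in the other 4, and Col3a1 8.27 and 3.69 against at most 0.193, while Fbln1 of the fibroblast list was lower there at 2.36 and 2.4957 against 3.99 to 5.66 FPKM. The median deviation of immediate early genes from their mean was -0.73 in the libraries numbered 3, where Fos was at 0.469 and 0.771 FPKM against 8.48 to 14.7 in the others. Jun and Btg2 of the same list were highest there, Jun at 33.7 or more against 20.8 to 25.1 FPKM and Btg2 at 13.6 and 12.5 against 5.32 to 7.89. The synaptic gene Arc was highest in those numbered 2 at 10.8 and 9.15 FPKM against 0.41 to 1.23. Npy measured 40.4 and 48.1 FPKM in the libraries numbered 1 and 125 to 216 in the others, and the astrocyte gene Gfap 16.4 and 13.9 against 3.401 to 4.23. Limma's F test over numbers called 16 of 17 immediate early genes, 7 of 7 fibroblast and meningeal markers and 15 of 15 mitochondrially encoded genes. It called 18 of 19 GABA receptor and inhibitory postsynapse genes and 6 of 9 genes of GABA synthesis, release and uptake. Of all genes tested it called 69.4%, which 6 of 9 does not exceed. Other lists lay on both sides of that share, with 15 of 15 oligodendrocyte lineage genes and 18 of 28 cell cycle genes.

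The grouping of libraries by replicate number was set against scaling, length and GC content. Of 8876 genes that differed between numbers, 7621 still did after centring each library, 7827 of 8871 after the length correction and 4697 of 8871 (52.9%) after the GC correction, so none of these alone accounts for the pattern. A GC trend is a candidate source of a large part of it, since the deviations of numbers 1, 2 and 3 correlated with GC content across genes at Spearman's rho of -0.70, 0.77 and -0.16 and the correction left 56.2% of the sum of squares. Separate cultures, days or library preparations stay open, as the labels do not say what a number stands for, and no biological explanation was tested. Pair differences between viruses carried GC trends of both signs (rho 0.23, 0.34 and -0.40).

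The lower immediate early and matrix lists under the block may come from the pair numbered 1. Without it 0 of these 2 lists passed, and their medians in the other pairs lay between -0.07 and 0.05. In that pair the fibroblast median was -0.98, and of the 13 fibroblast genes none is in the matrix or immediate early list. Swapping labels within pairs gave as many lists in 4 of 4 arrangements, the real one included, with 2 in the real one and 7, 9 and 6 in the others. The immediate early list was also called with the labels of pair 3 swapped, and with those of pairs 2 and 3 swapped. Its call therefore does not depend on the real labels of those pairs. The matrix list was called in the real arrangement alone. Pair 1 kept its labels throughout, and 4 arrangements are too few for a share under 0.05. An effect of the Brpf1 hairpin seen only in that pair stays open as well, since it holds 1 library per virus, although Brpf1 differed least in that pair (4.9% lower, against 16% and 21.8%).

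Sar1a was lower in all 3 pairs. Reads moved to its paralog Sar1b would raise that gene with AAV-shbrpf1, and it was higher in 0 of 3 pairs, while the sum of both genes was 36.2% lower. A shift between isoforms could lower an FPKM sum, as its longest transcript is 8.19 times its shortest and the level differed 3.2-fold, and gene values cannot tell this from less RNA. The smallest blocked limma p was 5.95e-05 in the real arrangement, that of Sar1a, and 6.47e-05, 1.56e-07 and 2.76e-05 with labels swapped within pairs. A p as small as that of Sar1a was thus seen in 3 of 4 arrangements, the real one included. These 4 are too few for a share under 0.05. A match of the hairpin to Sar1a, or an effect of lower Brpf1, stays untested.

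Between the groups without the block, the real counts of genes and lists were 0, which each of the 10 splits of the 6 libraries (10 of 10) must reach, so that these counts say nothing about chance. The highest other counts were 1 gene and 15 lists, and 10 splits are too few for a share under 0.05. Splits that part a single pair by number gave up to 5137 genes at an unadjusted p under 0.05 against 23 in the real one, which points to the structure by replicate number. The 4 splits that part all 3 pairs gave 0 genes each, and 0, 4, 4 and 1 lists with the real split first.

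The mitochondrial gene mt-Atp6 was listed at 5525 and 5413 FPKM in the libraries numbered 1 and at 110 to 179 FPKM in the other 4, and its nuclear copy Gm10925 at 5986 and 5884 against 656 to 1214 FPKM. Pet117 was listed near 0 in 4 libraries and at 18.5 and 7.98 FPKM in AAV-shbrpf1 libraries 2 and 3.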
